A study of Oncorhynchus mykiss with 60 samples.

How the data were processed

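Rainbow trout eggs and embryos were divided along the animal to vegetal axis into 5 sections, lettered A at the animal pole to E at the vegetal pole, and each section was sequenced as a library of its own. The labels give 60 libraries from 4 stages: 0 hours post fertilization (0 hpf), 1 hpf, 1 day post fertilization (1 dpf) and 3 dpf. Per the labels' protocols, RNA was extracted with TRI Reagent and precipitated with lithium chloride, ribosomal RNA was depleted and strand-specific libraries were made from the same mass of total RNA of every section. Each library is therefore a measure of a transcript's share of the reads counted for its section after ribosomal RNA depletion. The amount of RNA per section was not analysed here. The labels of the 0 hpf group name both an unfertilized egg and a freshly fertilized egg, and those of the 1 hpf group name both a 1-cell and an early cleavage stage, so the stages are called by their times. The labels call the samples biological replicates and say nothing of parents or clutches, so p-values measure the spread between these samples, which may be partly technical.

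The deposited values are whole-number read counts per gene, which per the submitters' processing notes came from fastp 0.23.4, STAR 2.7.11 and HTSeq 2.0.4. DESeq2 is also named in the submitters' processing notes, without a version. The genome build and the strand setting of the counting are not given in the sources used here, so no coordinates or gene lengths were used. The count table held 55 libraries. The 5 libraries of the 1 hpf replicate numbered 2 were not analysed here, which left 2 replicates at 1 hpf and 3 at each other stage, fewer than the 60 libraries that the planned design assumed. Of 23471 features, 23470 matched a gene of the RefSeq table for assembly USDA_OmykA_1.1, among them 22836 protein-coding genes, 498 lncRNAs, 72 snoRNAs and 13 rRNAs. Names were the trout symbol for 6163 features and the symbol of the zebrafish ortholog for 6834, and 10474 had neither. Duplicate copies of a gene, common in trout, carry their ID after the shared name where 2 copies are compared, and reads that fit both copies could have been divided or discarded in the counting, so the level of any single copy is uncertain to that extent.

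The total count per library ran from 1.09 to 14.46 M (median 4.6 M), and 21546 to 23336 genes had at least 1 count. A gene with no count in a library lay below the level of 3 counts, which was between 0.207 and 2.752 CPM, counts scaled to a common library total. The highest gene of any library took 0.503% of its counts. Replicates of the same section and stage differed beyond counting noise in each of 50 pairs, with a chi-square per degree of freedom of 2.63 to 19.43 (median 11.23). Repeat libraries of the same RNA can exceed counting noise as well, so this does not tell separate samples from repeats, and the replicates were taken as separate samples from the labels. Intervals and floors cover counting error only.

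Counts were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F-tests with TMM normalization, a filter on low counts (filterByExpr, minimum count 10) and Benjamini-Hochberg adjustment at 0.05. Within each stage, section and replicate entered the fit, all 4 section terms were tested together to call a gene localized, and section A was compared with section E. Stages were compared on counts summed over the 5 sections of each replicate, over 11 sums in 1 fit without a replicate term. The sums weight each section by its sequencing depth, which differed between sections and replicates. Redistribution was the difference between stages in the A minus E contrast, in 1 fit of the 55 libraries with 11 replicate terms. A gene said to move toward A or E changed in this contrast of relative levels, which does not show transport of its RNA. All adjusted p-values of genes come from these tests. Log2 fold changes are the fitted values with standard errors, and levels are means of TMM-scaled CPM over replicates with SDs where printed. A fold against a group without any count is a lower bound from 3 counts over that group. Genes with 1 to 3 counts in a group are given as levels without a fold, and redistribution is given without a size where a pole had 3 counts or fewer over the replicates of a stage.

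Replicates with the same number in different stages were compared through the correlation across genes of their deviations from the stage means. For the 3 pairs of 1 dpf with 3 dpf the correlations were 0.63, 0.51 and 0.72, so these numbers were taken to pair the samples. However, 1 dpf replicate 2 correlated with 3 dpf replicate 1 at 0.5, and 1 dpf replicate 1 with 3 dpf replicate 2 at 0.35. The data thus set number 3 apart and did not clearly pair numbers 1 and 2. The 0 hpf replicates showed values between -0.02 and 0.14 with later ones of the same number. The 2 pairs of 1 hpf with 1 dpf (0.58 and 0.66) and of 1 hpf with 3 dpf (0.45 and 0.66) were too few for the rule.

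Gene lists, designs, alternatives and the rule for named genes were fixed before the data were examined. Per comparison, the genes with the largest log2 change in each direction were taken in rank order, at most 10 (6 for redistribution), among named genes past the threshold with at least 10 CPM in the higher group and the same direction in every replicate. Up to 4 members of each list with the smallest adjusted p and a set of 14 fixed germ-line, axis and oocyte genes were added. Some genes that the rule names are not reported here. The 18 lists hold genes of the germ plasm, vegetal and dorsal determinants, oocyte and egg genes, cell cycle, regulators of zygotic genome activation, zygotic patterning, envelope and periderm, yolk syncytial layer, mRNA clearance, RNA localization and motors, ribosomal proteins, histones, stress and immediate-early genes, mitochondrially encoded genes, and markers of follicle cells, blood, liver and yolk precursors, and sperm and testis. No mitochondrially encoded gene matched a feature, so that list gave no result. Zebrafish names shared by 9 or more trout genes, 5 names in all, were left out of the name matching after the table had been read, and ribosomal S6 kinases were taken out of the ribosomal protein list. Lists of at least 3 measured members were tested against all other genes with camera from limma 3.58.1, at a preset correlation of 0.01. Of 175 such tests 58 passed, and none passed with an estimated correlation, so every list result below is a count and a preset-correlation test only. The list's median, mean and test differed in sign in 26 of the 175, none of which passed.

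The position of the main step along the axis was added after a principal component plot had been seen. For each replicate the squared difference in log2 CPM between neighbouring sections was averaged over 11049 genes of at least 20 CPM, less the part due to counting, and each step was given as its share of the sum over the steps A to B, B to C, C to D and D to E. Alternatives were library-size scaling, no filter, a joint fit, no replicate term or a replicate term across stages, fits of only the stages compared, equal weight for each section, a minimum fold change of 2, a linear trend, DESeq2 1.42.0, and leaving out each replicate. Where leaving out a replicate left a single 1 hpf sample, the spread came from the other groups, and that sample was assumed to vary like them. Replacing TMM by library size shifted the median A minus E of all genes by 0.19 at 0 hpf, 0.2 at 1 hpf and 0.3 at 1 dpf, and the median redistribution by -0.4 from 1 dpf to 3 dpf and -0.27 from 0 hpf to 3 dpf, and all changes below are relative to the TMM scaling. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, the A against E test recovered 90% and 100% at 0 hpf, 66% and 91% at 1 hpf, 82% and 99% at 1 dpf and 48% and 95% at 3 dpf. The stage test recovered 1% and 76% for 1 hpf against 0 hpf, 4% and 71% for 1 dpf against 1 hpf, and 8% and 87% for 3 dpf against 1 dpf. For redistribution the shares were 39% and 93%, 43% and 86%, 34% and 91%, and 42% and 92%, in the order 0 to 1 hpf, 1 hpf to 1 dpf, 1 to 3 dpf and 0 hpf to 3 dpf.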

Results

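Transcripts were counted in 5 sections along the animal to vegetal axis of rainbow trout eggs and embryos at 4 stages. The animal pole, section A, holds the germinal disc from which the embryo forms, and section E holds the vegetal end of the yolk. Counts of 55 libraries were analysed, from 3 replicates at 0 hpf, 2 at 1 hpf, 3 at 1 dpf and 3 at 3 dpf. Totals per library, in M counts, were 2.34 to 14.46 at 0 hpf (median 5.38), 2.89 to 8.06 at 1 hpf (4.96), 3.22 to 8.0 at 1 dpf (5.28) and 1.09 to 6.81 at 3 dpf (3.86). The title of the series names the redistribution of localized RNA as its subject. Each stage was therefore read along the axis, and the stages were then compared in total level and in the position of their transcripts.

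At 0 hpf the animal and vegetal poles held different transcripts. The largest excess in section A was that of huwe1, a HECT-type ubiquitin ligase, at 178 ± 34.6 CPM in A and 7.44 ± 3.72 in E (SD, n = 3, log2 4.72, SE 0.31, adjusted p = 1.89e-09). Next came birc6 (LOC110502424, 4.70, SE 0.31), a very large ubiquitin-conjugating inhibitor of apoptosis, and ubr4 (4.60, SE 0.28), a ligase that recognizes protein ends. The very large adhesion receptor adgrv1 was at 4.52 (SE 0.28) and the huwe1 copy LOC110531242 at 4.51 (SE 0.33). The spliceosome core gene prpf8 (4.40), the dynein heavy chain dync1h1 (4.32, 115 ± 59.1 against 5.86 CPM) and the other birc6 copy (4.22) followed. The ribosome assembly ATPase mdn1 (4.2) and the spliceosomal helicase snrnp200 (4.19) completed the first 10. Without replicate 1 the values were higher for birc6 (5.44 for LOC110502424, 4.95 for the other copy), huwe1 LOC110531242 (5.23) and snrnp200 (5.11). Several of these genes encode very large proteins, and transcript length was not tested because no gene models were used.

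At the vegetal pole of 0 hpf the largest excess was that of pip4p2, a phosphoinositide phosphatase, with 1.85 ± 0.66 CPM in A and 178 ± 54.4 in E (-6.55, SE 0.39, adjusted p = 6.63e-10, n = 3). It was followed by hwa (-6.26, SE 0.31, 1.5 against 112 CPM), which encodes Huluwa, a maternal membrane protein that zebrafish need to form the dorsal organizer. The grip2a/grip2b gene LOC110492486, whose zebrafish counterpart acts in the transport of dorsal determinants, was at -6.14 (SE 0.39, 19.8 against 1450 CPM). The hwa copy LOC110509564 was at -6.14 as well, or -5.51 without replicate 3. Then came the calcium channel regulator cracr2b (-6.08) and trim36 (LOC110525254, -5.97, 39.9 against 2500 CPM), a ubiquitin ligase whose vegetal transcript in frogs is needed for dorsal axis formation. The importin kpna3 was at -5.79, klhl8 LOC110536911 at -5.78 (its other copy was higher in A, 0.62), the chromatin remodeller ino80 at -5.47 and slbp2, the oocyte protein that binds histone mRNA, at -5.42 (32.7 against 1270 CPM). Each of these 20 genes had the same direction in all 3 replicates, which the naming rule required.

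Germ plasm genes leaned toward E at 0 hpf, with 16 of 26 measured genes higher in E and 3 in A (16 and 3 adjusted over the list alone). The camera test gave an adjusted p of 0.00137, and adjusted p = 0.288 with an estimated correlation. The germ-cell RNA-binding gene dazl was at -4.41 (SE 0.26, 19 against 373 CPM) and its copy LOC110487980 at -2.06. The RNA-binding gene celf1 was at -3.8, dazap2 at -4.26, ddx4, which encodes the Vasa helicase, at -1.25, and dnd1 at -0.75. On the animal side, the Tudor-domain gene tdrd6 had a mean log2 A minus E of 3.45 (SD 0.29, n = 3), and of 2.67 at 1 hpf (SD 0.42, n = 2). The 3 copies of buc, whose protein organizes the Balbiani body of the oocyte, were at -2.13 (264 against 1170 CPM), -3.05 and -1.13. Of 23 vegetal and dorsal determinants, 16 were higher in E and 4 in A (16 and 4 adjusted over the list alone). Their camera adjusted p was 0.00137, with adjusted p = 0.138 with an estimated correlation. Both copies of the motor adaptor sybu (-4.7 and -4.36) and grip2b (-3.96) were among them. The germ-line gene nanos3 LOC110493386 (-1.13) and the signal wnt8a (-3.52, 1.12 ± 1.85 against 13.9 ± 23.7 CPM) did not pass without the replicate term. The growth factor gdf3 (-0.48) was lost without replicate 1 or 2 or with library-size scaling. The same scaling ended the calls of nanog (-0.58, also lost without replicate 3) and of its copy LOC110535236 (-0.51, also lost without replicate 1).

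Ribosomal protein transcripts leaned toward A at 0 hpf, where 69 of 133 were higher and 5 lower (67 and 5 adjusted over the list alone), for example rpl5b (1.8) and rpl11 (1.52). By camera the list's adjusted p was 4.48e-06, and adjusted p = 0.45 with an estimated correlation. Regulators of zygotic genome activation were higher in A for 33 of 60 and lower for 12 (34 and 13 adjusted over the list alone). Against all other genes camera gave an adjusted p of 0.0206, and adjusted p = 0.554 with an estimated correlation. Among them znf462 was at 2.7 and the pluripotency factor pou5f3 at 0.85, while the pou5f3 copy LOC110523509 did not pass (0.33, adjusted p = 0.0776), though it did with library-size scaling (0.53) or without replicate 1 (0.57). In the stress list 12 of 21 genes were higher and 5 lower in A (camera adjusted p = 0.105). The smallest adjusted p in it were those of the chaperones hspa8 (2.93, SE 0.13, 325 against 43.7 CPM), hsp90ab1 (2.94, 367 against 48.5 CPM), hsp90bb (3.17) and hspa8b (3.1).

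Oocyte genes lay at both poles of 0 hpf, 7 of 26 higher in A and 15 in E (camera adjusted p = 0.226). The poly(A)-binding gene pabpc1l and zar1l were at 2.15 and 1.79. The growth factors bmp15 and gdf9 were at -2.04 and -1.51 and the deadenylation adaptor btg4 at -0.66, while zar1 (0.29, adjusted p = 0.144) passed with library-size scaling (0.48) only. Of 65 cell cycle genes 26 were higher and 25 lower in A, with a median of -0.17, a mean of 0.16 and a camera adjusted p of 0.74. The replication helicase genes mcm4 and mcm2 were at 2.59 and 1.94. The 3 ccnb1 copies, which encode the mitotic cyclin B1, were at -0.95, 0.95 and 0.5, and the last (LOC110523559) was lost without replicate 3 (0.41) or without the replicate term.

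The other lists did not pass camera at 0 hpf. Of 65 mRNA clearance genes 30 were higher and 13 lower in A (adjusted p = 0.0802), with cnot1 at 2.32 and pan3 at -2.96. Library-size scaling gave this list an adjusted p of 0.0429 and the fit without the replicate term 0.0293. Of 49 localization and motor genes 19 were higher and 18 lower (0.745), with the kinesin kif5ba/kif5bb at 2.35, and of 17 envelope and periderm genes 7 and 7 (0.649). Of 6 yolk syncytial layer genes 4 were lower (0.229), and of 5 histone genes 2 were higher and 1 lower, with h1m at 1.69 and h2ax at -1.47. Markers of other cells gave 1 higher and 2 lower of 5 for follicle cells (0.725), 3 lower of 3 for liver and yolk precursors (0.11) and 1 and 1 of 5 for sperm and testis (0.731). The single measured blood marker was not called.

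In all, 12226 of 21799 genes (56.1%) were localized at 0 hpf by the edgeR quasi-likelihood test over the 5 sections. Of the genes, 6965 were higher in A and 6981 in E, and 3806 and 3177 of them differed at least 2-fold. With library sizes in place of TMM factors the split was 8388 against 5339. Without the replicate term 7743 genes were localized, and 7490 without replicate 3.

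At 1 hpf, with 2 replicates, the first gene on the vegetal side was klhdc8b, a kelch-domain gene, but its level in E differed between replicates (0.564 against 122 ± 169 CPM, -7.69, SE 0.32). It did not pass without the replicate term, and it was at -6.69 without replicate 3. Then came slbp2 (-7.24, SE 0.38, 12.5 against 1870 CPM, adjusted p = 4.59e-07). The potassium channel gene kcnq5b stood at 0.113 against 18.6 CPM (adjusted p = 2.96e-06) and card19 at 0.295 against 20.5 CPM (adjusted p = 9.09e-06), with kpna3 between them (-6.73, SE 0.34). Next were hwa (-6.59, 1.88 against 178 CPM), gipc2 (-6.52, or -7.15 without replicate 3), pip4p2 (-6.5), the grip2a/grip2b gene LOC110492486 (-6.49, 14.1 against 1240 CPM) and trim36 (LOC110525254, -6.47, 30.6 against 2760 CPM).

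In section A of 1 hpf the beta-actin gene actb led at 3.95 (SE 0.35, 21.6 ± 7.59 against 1.37 ± 0.576 CPM, adjusted p = 9.46e-06). The nuclear pore gene nup133 (3.71) came next but did not pass without the replicate term or without replicate 1. Then came birc6 LOC110502424 (3.68, or 2.9 without replicate 3), ccser2b (3.59, or 4.75 without replicate 3) and ubr4 (3.56, SE 0.28, 82 against 6.94 CPM). The histone methyltransferase kmt2d (LOC110532701) was at 3.55, or 4.36 without replicate 3. The kinetochore gene cenpf was at 3.09 (SE 0.26, 507 against 61.7 CPM). Ribosomal protein genes were higher in A for 109 of 140 and lower for 2 (113 and 3 adjusted over the list alone), with rpl13a at 2.19 and rs5 at 2.2. The camera test returned an adjusted p of 4.73e-16, and adjusted p = 0.146 with an estimated correlation.

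Germ plasm genes at 1 hpf were higher in E for 16 of 26 and in A for 3 (camera adjusted p = 0.00142, adjusted p = 0.513 with an estimated correlation). The germ-line gene dazl was at -5.36 (9.19 against 361 CPM), celf1 at -4.97, ddx4 at -1.73 and buc at -2.43 with copies at -3.49 and -1.22. Of 22 vegetal and dorsal determinants 15 were higher in E and 4 in A (16 and 4 adjusted over the list alone). Their camera adjusted p was 0.000594, and adjusted p = 0.281 with an estimated correlation, and the sybu copies were at -5.42 and -5.85. The endoplasmic reticulum chaperones hspa5 and grp94 were at -2.01 and -1.87, on the vegetal side, whereas the cytosolic hsp90ab1 was at 2.25. The edgeR test called 9985 of 21644 genes (46.1%) localized, with 5972 higher in A and 5395 in E, or 7490 and 3935 with library-size scaling. Without the replicate term 4227 genes were localized and 3191 and 2974 differed between the poles, and without replicate 3 the poles held 3136 and 3536.

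At 1 dpf the largest excess in section A was that of the forkhead gene foxq1a (LOC118946460), which stood at 29 ± 28.2 CPM in A against 0.159 ± 0.144 in E (adjusted p = 1.91e-08, n = 3). Then came sox19a (LOC110534223), a SoxB1 factor of the early embryo, at 5.2 (SE 0.25, 46.7 ± 42.7 against 1.28 ± 1.14 CPM, adjusted p = 3.2e-11). The finTRIM gene ftr82 was at 4.88 (3.74 without replicate 1), the zinc-finger regulator sall1a at 4.82 (SE 0.57, 30.3 ± 27 against 1.04 CPM) and stard13b at 4.72 (3.89 without replicate 1, 5.53 without replicate 3). The spliceosome gene snrpd1 (4.52, SE 0.39), the elongation factor eef2b (4.52, 113 against 5.56 CPM, or 5.12 without replicate 3), rpl3 (LOC110486633, 4.5) and dync1h1 (4.47, 87.7 against 4.59 CPM) followed. The BMP antagonist chrd (LOC110504089) was at 4.38 (SE 0.95, 13.2 ± 11 against 0.644 CPM, adjusted p = 0.000749), but did not pass without replicate 1 (3.21) and was at 5.06 without replicate 3. In section A chrd stood at 22.4 and 16.1 CPM in replicates 1 and 2. In replicate 3 it stood at 1.01 CPM in A and 0.697 in E.

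At the vegetal pole of 1 dpf the first were pip4p2 (-7.1, or -7.79 without replicate 2) and hwa (-6.98, SE 0.58, or -6.29 without replicate 1). The kelch gene klhdc8b (-6.95, 0.673 against 89.9 ± 152 CPM) did not pass without the replicate term. The grip2a/grip2b gene LOC110492486 was at -6.93 (SE 0.65, 19.3 against 2140 ± 923 CPM), trim36 LOC110525254 at -6.66 (SE 0.46, 42.3 against 4160 CPM) and slbp2 at -6.48. The glycosyltransferase galnt1 was at -6.38, or -8 without replicate 1. Of 29 germ plasm genes 16 were higher in E and 7 in A (camera adjusted p = 0.0027, adjusted p = 0.294 with an estimated correlation). Among them dazl was at -4.91, celf1 at -4.77 and ddx4 at -1.99, while the Tudor-domain gene tdrd6 was at 3.48 (175 against 16.4 CPM). Of 26 vegetal and dorsal determinants 14 were higher in E and 5 in A (14 and 6 adjusted over the list alone). By camera the list's adjusted p was 0.0343, and adjusted p = 0.516 with an estimated correlation. The Balbiani body gene buc was at -2.18 with copies at -3.41 and -1.34.

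Ribosomal protein genes were on the animal side at 1 dpf, 122 of 141 higher and 2 lower in A (125 and 3 adjusted over the list alone). Against all other genes camera gave an adjusted p of 1.4e-14, and adjusted p = 0.138 with an estimated correlation. Of 67 regulators of genome activation 41 were higher and 10 lower (camera adjusted p = 0.00422, adjusted p = 0.558 with an estimated correlation), with sox19a LOC110500375 at 1.59 (425 against 146 CPM) and pou5f3 at 0.87. The nanog copy LOC110535236 was at 2.39 (159 ± 129 against 24.8 CPM), a call lost without replicate 1 (1.55) or 2 (1.91), and 3.28 without replicate 3. In section A this copy stood at 251 and 215 CPM in replicates 1 and 2. Replicate 3 went the other way, with 11.4 CPM in A and 24.4 in E. The other nanog gene was at -0.66. Of 26 zygotic patterning genes 12 were higher and 4 lower (13 and 5 adjusted over the list alone, camera adjusted p = 0.493). The head factor otx2b (LOC110522467) was at least 22.5-fold higher in A (adjusted p = 1.88e-06). The neural gene her5 was at least 33.8-fold higher but did not pass without the replicate term or with DESeq2. The nanos3 copies LOC110495041 and LOC118938533 stood at 5.77 and 13.4 CPM in A against 0.0933 CPM each in E, the first lost without replicate 1 and the second with DESeq2. The edgeR test called 13810 of 22141 genes (62.4%) localized at 1 dpf, with 7281 higher in A and 6755 in E, or 9659 and 4620 with library-size scaling.

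At 3 dpf the largest excesses in section A were of genes without a count in E in any of 3 replicates. The endoderm factor sox32 was at least 81-fold higher in A (30.2 ± 12.4 CPM, adjusted p = 4.56e-05) and the antiproliferative gene btg1 at least 86.4-fold (32.2 ± 6.62 CPM). The proteoglycan cspg4b was at least 71.7-fold higher, the Mediator subunit med13a at least 68.5-fold, the phosphodiesterase pde6b at least 48.5-fold and the zinc-finger gene znf770 at least 57.8-fold. At the vegetal pole the syntrophin sntg1 was at least 82.9-fold lower in A (23 ± 23.6 CPM in E), and klhdc8b stood at 0.214 against 89.5 ± 152 CPM (adjusted p = 2.2e-09). The dorsal gene hwa was at -8.12 (SE 0.43, 0.863 against 263 CPM, or -8.74 without replicate 1). The grip2a/grip2b gene LOC110492486 was at -7.61 (SE 0.46, 14 against 2670 CPM), and hwa LOC110509564 at -7.19 (-9.11 without replicate 1, -6.22 without replicate 3). The ephrin receptor epha5 stood at 0.253 against 31.5 CPM, trim36 (LOC110525254) was at -6.77 (SE 0.38, 43.3 against 4430 CPM) and slbp2 at -6.55 (-7.51 without replicate 1).

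Of 44 zygotic patterning genes 40 were higher and 4 lower in A at 3 dpf, with a median of 5.51, or 5.37 with genes at 0 counts set at their bound. The camera adjusted p was 4.92e-07, and adjusted p = 0.192 with an estimated correlation. The chordin copy chrd LOC110504089 was at 6.51 (SE 0.61, 72.6 ± 39.1 against 0.666 CPM) and the ventral repressor vox at 6 (460 against 6.11 CPM, or 7.99 without replicate 2). The signal fgf8a was at 5.98 (5.38 without replicate 2, 6.82 without replicate 3) and wnt8a at 3.78 (3.03 without replicate 1, 4.66 without replicate 3). All 145 ribosomal protein genes were higher in A (median 4.55), such as rps3 (4.85, 246 against 8.23 CPM). The camera test returned an adjusted p of 8.27e-25, and adjusted p = 0.335 with an estimated correlation. Of 70 genome activation regulators 55 were higher and 9 lower (camera adjusted p = 1.52e-05, adjusted p = 0.332 with an estimated correlation). Here nanog LOC110535236 was at 5.08 (SE 0.36, 1520 against 44.5 CPM, or 5.79 without replicate 2) and pou5f3 at 2.51 (1780 against 312 CPM). In contrast sox3 and tbp were at -3.37 and -3.15, and the other nanog gene did not pass (-0.22, adjusted p = 0.163).

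Envelope and periderm genes were higher in A at 3 dpf for 16 of 24 and lower for 3 (camera adjusted p = 0.0035, adjusted p = 0.137 with an estimated correlation). The epithelial regulator grhl3 was at 5.54 (112 against 2.3 CPM). Stress genes were higher for 16 of 25 and lower for 4 (17 and 4 adjusted over the list alone), with hsp90ab1 at 5.19 (2990 against 80.3 CPM) and junbb at -3.38. Their camera adjusted p was 0.0225, and adjusted p = 0.138 with an estimated correlation. The 5 histone genes were all higher (camera adjusted p = 0.0499, adjusted p = 0.336 with an estimated correlation). Of 65 clearance genes 41 were higher and 13 lower (42 and 13 adjusted over the list alone), with the Argonaute gene ago2 LOC110488009 at 6.2 (7.5 without replicate 2). By camera the list's adjusted p was 0.00817, and adjusted p = 0.59 with an estimated correlation. Of 9 yolk syncytial layer genes 7 were higher and 1 lower (camera adjusted p = 0.106), with mxtx1 at 3.13.

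Oocyte genes lay on the vegetal side at 3 dpf, 19 of 26 higher in E and 4 in A (camera adjusted p = 0.00137, adjusted p = 0.293 with an estimated correlation). The values were -3.54 for btg4, -2.83 for bmp15, -2.75 for the oocyte transcription factor figla and -1.46 for zar1. Of 29 germ plasm genes 17 were higher in E and 6 in A (camera adjusted p = 0.0128, adjusted p = 0.41 with an estimated correlation). Here dazl was at -5.5 (-6.38 without replicate 1), celf1 at -4.7, buc at -3.21 and ddx4 at -1.63, while dnd1 (-0.4, adjusted p = 0.126) passed without replicate 3 (-0.69). The nanos3 copies diverged, with LOC110493386 at -2.11 and LOC110495042 at 5 (72.9 against 2.01 CPM, or 5.92 without replicate 2). The nanos3 copy LOC118938533 was at 5.83 (115 against 1.66 CPM, or 8.44 without replicate 2), and LOC110495041 stood at 49.2 against 0.0875 CPM. The cell cycle list held 33 higher and 21 lower of 68 (camera adjusted p = 0.344), with cenpf at 4.43 (1120 against 53.9 CPM) and incenp at 3.94. The vegetal and dorsal determinant list held 19 higher and 12 lower of 32, with a median of 0.97 but a downward test (camera adjusted p = 0.971). Only 23 of its genes were measured at 0 hpf, so the counts of these stages do not cover the same genes. Of the 32 genes, 12 are also in another list. The maternal hwa, grip2a/grip2b LOC110492486 and trim36 LOC110525254 were among the lower ones. The edgeR test called 15622 of 22380 genes (69.8%) localized at 3 dpf, with 8526 higher in A and 7685 in E, and 7002 and 5922 of them at least 2-fold.

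**Figure D1:**
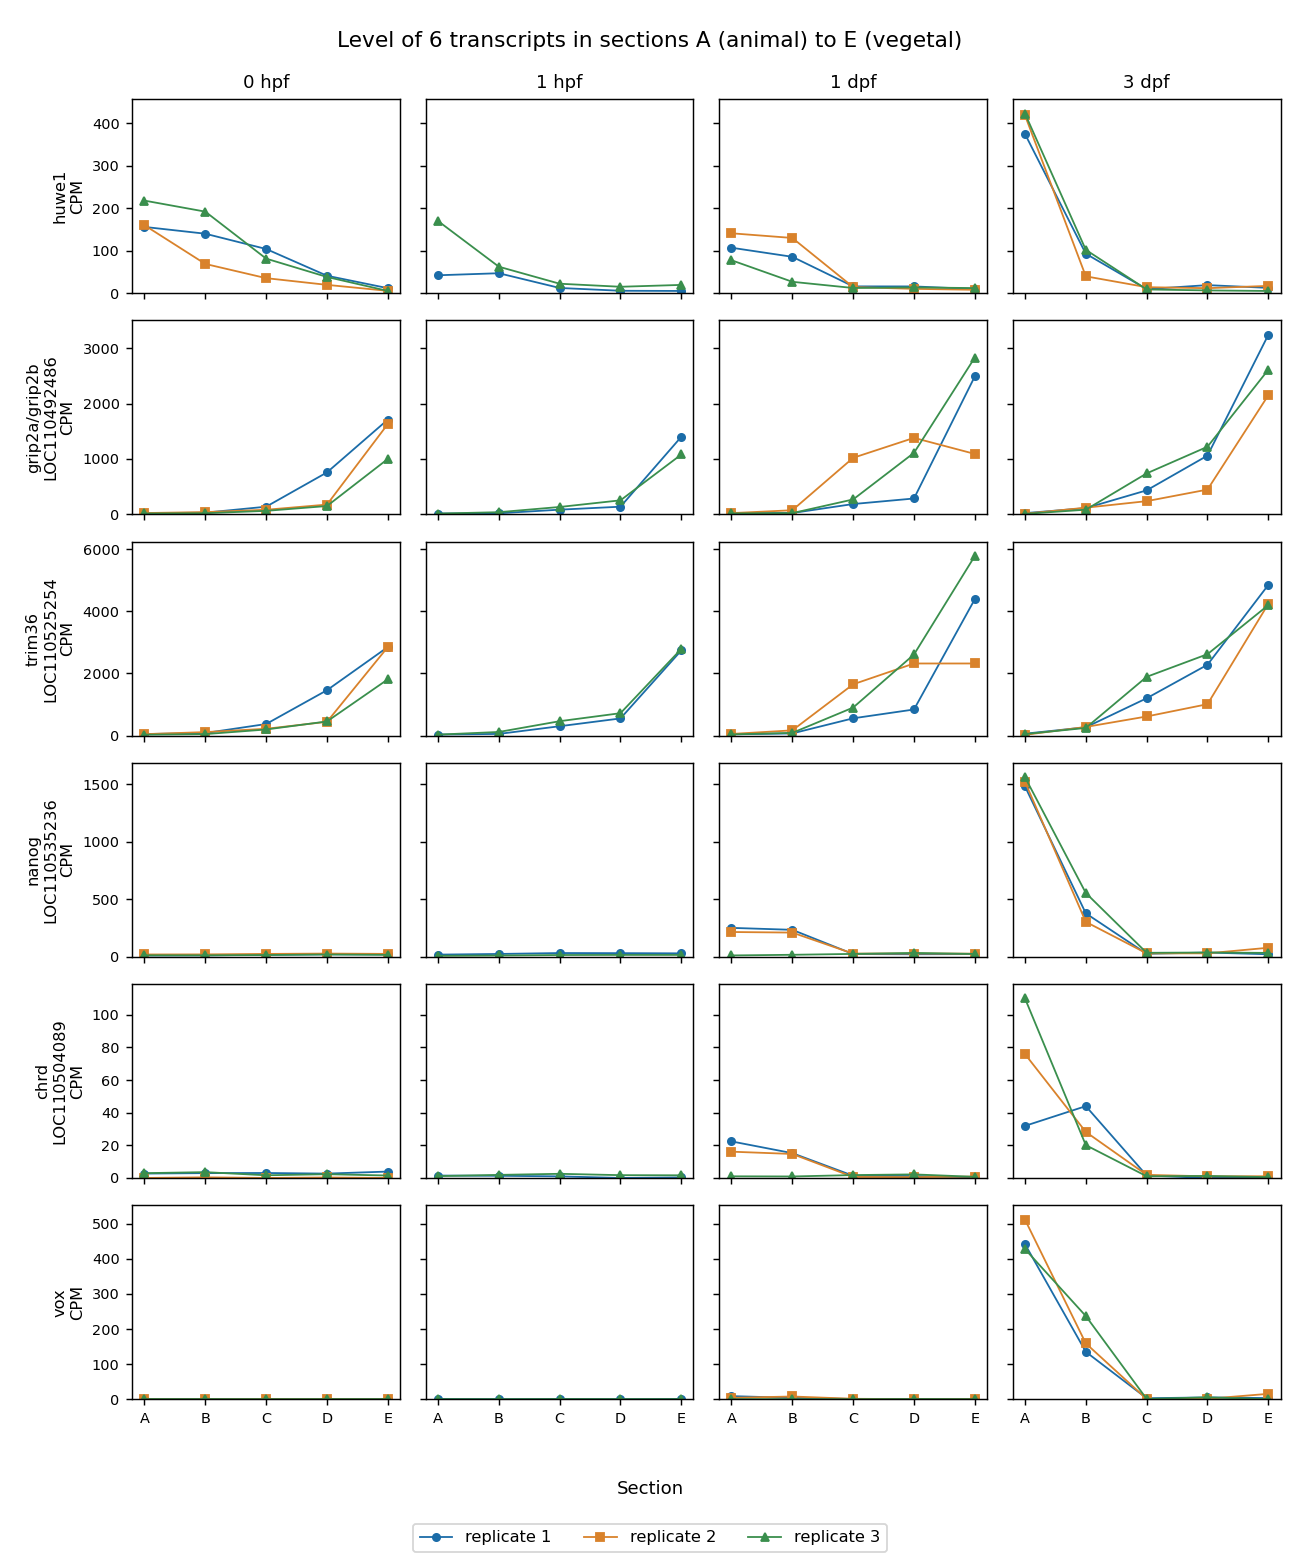
CPM (y axis, shared within a row) in sections A to E (x axis) for 6 transcripts at the 4 stages, with 1 line per replicate. At 0 hpf huwe1 fell from 178 CPM in A to 7.44 in E, grip2a/grip2b and trim36 were higher in E than in A at every stage, and nanog LOC110535236, chrd LOC110504089 and vox were higher in A than in E at 3 dpf.

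Up to 1 dpf nearly all genes called in both of 2 successive stages kept their pole. Of 6824 genes higher in A at 0 hpf and tested at 1 hpf, 5262 were higher in A at 1 hpf (1910 if the calls were independent) and 3 were higher in E. From 1 hpf to 1 dpf 5336 genes shared the animal side (1912 if independent) and 4958 the vegetal side (1687), and 0 and 9 changed side. From 1 dpf to 3 dpf 5110 genes shared the animal side (2554 if independent) and 5069 the vegetal side (2398), while 472 went from A to E and 442 from E to A.

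The profile between the poles differed in shape. At 1 dpf the step from B to C held 87 ± 3.4% of the squared log2 differences between neighbouring sections (SD, n = 3), against 29.9 ± 7.3% at 0 hpf (n = 3). It held 66.9 ± 26.3% at 1 hpf (n = 2) and 35.6 ± 11.5% at 3 dpf (n = 3), where the step from A to B held 56.9 ± 14.4%. At 0 hpf the differences were spread over B to C, C to D (24.5 ± 10.5%) and D to E (34.8 ± 10.6%). An exact two-sided permutation test of the B to C share gave p = 0.1 for 0 hpf against 1 dpf, the smallest that 3 against 3 can give. The same exact test gave p = 0.4 for 0 hpf against 3 dpf and p = 0.0485 for 0 hpf against the 8 later replicates, which are not independent of each other because later samples of the same number resembled each other. These tests were chosen after the profiles had been seen.

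**Figure D2:**
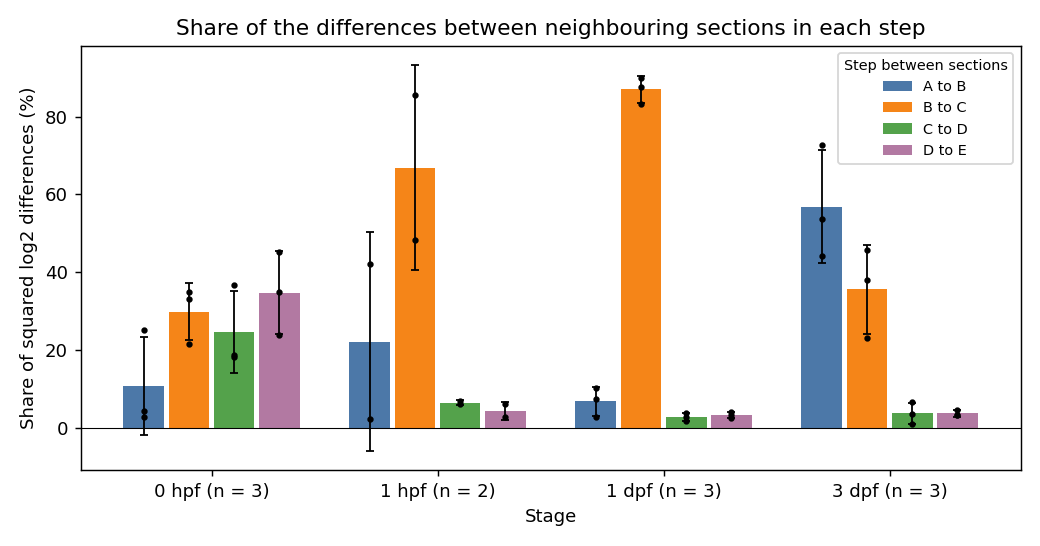
Share (%, y axis) of the squared log2 differences between neighbouring sections that fell in each step along the axis, by stage (x axis), with bars for the mean, points for replicates and error bars for the SD. The step from B to C held 29.9% at 0 hpf and 87% at 1 dpf, and the step from A to B held 56.9% at 3 dpf.

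Between 0 hpf and 1 hpf a limited set of genes differed in summed level. Those with the largest excess at 1 hpf were barely detected at 0 hpf (n = 2 and 3). The myosin gene smyhc1 stood at 11.6 CPM against 0.0189 at 0 hpf (adjusted p = 0.0004), klhl14 at 15.2 against 0.0278 (6.95e-05) and the lipid transfer gene cetp at 14.3 against 0.0173 (0.00152). The chemokine receptor cxcr3.2 was at 8.25 (29.1 against 0.131 CPM, adjusted p = 0.000497), a call lost when only these stages were fitted, with 9.9 without 0 hpf replicate 2 and 7.48 without 0 hpf replicate 3. The neural adhesion gene cntn4 was at 11.4 against 0.0434 CPM, and the guidance molecule rgma at 7.65 (SE 0.47, 45.2 against 0.191 CPM, adjusted p = 6.01e-05). In the other direction pdlim1 was at least 578-fold lower at 1 hpf (33 CPM at 0 hpf, adjusted p = 0.0031) and the adhesion gene mcama at least 197-fold lower (11.2 CPM at 0 hpf, 0.00115). The receptor ephb6 stood at 0.0295 against 20.7 ± 17.9 CPM (0.0448, lost without either 1 hpf replicate). The stereocilia gene loxhd1b was at -7.81 (SE 0.72, 0.0831 against 18.7 CPM, 0.000596).

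Of the genes fixed beforehand, bmp4 was lower in total level at 1 hpf than at 0 hpf by 2.08 (SE 0.27, 10.5 against 44.7 CPM, adjusted p = 0.00429). The motor kif1b (-1.3, 0.00236) was lost when only these stages were fitted, and zar1 (-0.84, 0.0175) also without either 1 hpf replicate or without 0 hpf replicate 1 or 3. Not past the threshold were hwa (0.77, adjusted p = 0.0619), celf1 (0.63, 0.0799), buc (0.38, 0.199), dazl (0.4, 0.274) and ddx4 (0.17, 0.575). Without 0 hpf replicate 2, hwa (0.93), celf1 (0.82) and dazl (0.66) passed, and hwa and celf1 did with DESeq2 (0.76 and 0.62). None of them passed with each section weighted alike. In 0 hpf replicate 1 sections D and E had 3.06 and 3.66 M counts, against 8.44 to 11.2 M in A to C. In replicate 2 they had 3.38 and 4.64 M against 2.34 to 4.09 M. Leaving out replicate 2 therefore gives the vegetal sections less weight in the 0 hpf sums. Of 5 follicle cell markers 2 were lower and 0 higher (2 and 0 adjusted over the list alone), with a median of -1.15. Against all other genes camera gave an adjusted p of 0.0492, and adjusted p = 0.264 with an estimated correlation. The lower pair were the connective tissue collagens col1a1a and col1a1b, and both were lost without 1 hpf replicate 1 or 0 hpf replicate 1 or 3, and col1a1b also without 1 hpf replicate 3. Of 65 clearance genes 3 were lower and 0 higher (6 and 4 adjusted over the list alone, camera adjusted p = 0.0239, adjusted p = 0.617 with an estimated correlation). Of the 2 blood markers 0 were called (1 higher and 1 lower adjusted over the list alone), and of the liver and yolk precursor markers 0 (camera adjusted p = 0.431).

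In all, the edgeR test called 519 genes higher and 297 lower at 1 hpf than at 0 hpf among 23460, and these counts moved widely. DESeq2 gave 1464 and 1468, and a fit of only these stages 21 and 13. Without 0 hpf replicates 1, 2 and 3 in turn the higher genes numbered 135, 1887 and 117 and the lower genes 54, 1220 and 51. Without 1 hpf replicate 1 the counts were 125 and 32, and without 1 hpf replicate 3 they were 312 and 590.

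Between 1 hpf and 1 dpf 0 genes passed the edgeR test in total level, with 679 of 23460 at an unadjusted p under 0.05, while DESeq2 called 10 higher and 1 lower. At adjusted p = 1, klf17, a zinc-finger factor, stood at 21.7 ± 20.6 CPM at 1 dpf and 0.071 at 1 hpf, and nanog LOC110535236 at 86.7 ± 59.8 and 20.2 ± 10.1 (n = 3 and 2). The grip2a/grip2b gene LOC110492486 stood at 623 and 282 CPM, trim36 LOC110525254 at 1230 and 698, buc at 770 and 754 and ddx4 at 235 and 220. As a group, the zygotic patterning list lay above other genes without a called member, with a median of 1.75, or 1.58 with genes at 0 counts at their bound. Its camera adjusted p was 5.59e-10, and adjusted p = 0.312 with an estimated correlation. The summed level of this list in section A was 213 and 206 CPM in 1 dpf replicates 1 and 2. In 1 dpf replicate 3 it was 111 CPM, near the 108 and 94.8 CPM of the 1 hpf replicates. The ribosomal proteins lay below other genes, again without a called member (median -0.2, camera adjusted p = 6.72e-11, adjusted p = 0.558 with an estimated correlation). Leaving out 1 dpf replicate 3 gave 97 higher and 5 lower genes.

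Between 1 dpf and 3 dpf the genes that rose most in total level were near or at 0 counts at 1 dpf. First was slc22a5, a carnitine transporter, at 227 ± 162 CPM against 0.013 (adjusted p = 0.000503, n = 3), then apoa-i-1, an apolipoprotein, at least 1080-fold higher (41.8 CPM, 0.000367). The neural factor bhlhe22 (LOC110489682) was at least 766-fold higher (0.00737), ftr14 stood at 99.2 ± 81.8 against 0.0284 CPM, and the endoderm and liver regulator hnf4a was at least 393-fold higher (15.2 CPM, 0.00715). The endoderm factor sox32 stood at 36.6 against 0.0142 CPM (0.000621), apoc1 LOC110537939 at 22.1 against 0.0142, and the Nodal ligand ndr1 at 18.4 against 0.0118 (0.00149). The genes that fell most were btr26 (-1.94, SE 0.37) and the actin regulator cyfip2 (-1.8, SE 0.34), both lost without the libraries numbered 3 of the later stages. Next were ccser2b (-1.74), lost without any single replicate, and the transcriptional regulator spen (-1.73, SE 0.18, 29.9 against 98.7 CPM, adjusted p = 0.000621).

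Zygotic patterning genes rose from 1 to 3 dpf for 28 of 44 and fell for 0 (35 and 0 adjusted over the list alone, median 4.07). The camera test returned an adjusted p of 5.92e-25, and adjusted p = 0.138 with an estimated correlation. The ventral repressor ved rose by 7.81 (SE 0.39, 68.2 against 0.298 CPM, adjusted p = 5.24e-05), the mesoderm factor tbx16 LOC110523532 by 7.57 (60.9 against 0.315 CPM, or 8.39 without 1 dpf replicate 1) and chrd LOC110507926 by 6.42. Ribosomal protein genes rose for 136 of 145 (142 adjusted over the list alone), such as rpl17 (3.73), with a median of 2.39. Their camera adjusted p was 9.46e-77, and adjusted p = 0.138 with an estimated correlation. Yolk syncytial layer genes rose for 7 of 9 (7 adjusted over the list alone, camera adjusted p = 1.86e-07, adjusted p = 0.098 with an estimated correlation). Among them the lipoprotein gene apoe was at 9.38 (SE 0.54, 124 against 0.182 CPM).

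Genome activation regulators rose from 1 to 3 dpf for 13 of 70 and fell for 3 (17 and 3 adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.558 with an estimated correlation). The nanog copy LOC110535236 (2.33, 441 against 86.7 CPM, adjusted p = 0.032) was lost without 1 dpf replicate 2 or 3 dpf replicate 1 or 3. Of pou5f3 (0.66, 0.0262) the call was lost without any 1 dpf replicate or 3 dpf replicate 1 or 3. The replication licensing gene cdt1 rose by 5.94 (330 against 5.33 CPM). Oocyte genes fell for 5 of 26 and rose for 0 (6 and 0 adjusted over the list alone), with a median of -0.33. By camera the list's adjusted p was 0.000368, and adjusted p = 0.098 with an estimated correlation. In this list zar1 was at -0.77, zar1l at -0.95 and npm2b at -0.94 and -0.9, and zar1l and npm2b were lost without the libraries numbered 3. Without 3 dpf replicate 3 both npm2b copies were lost, and the second without any single replicate other than 1 dpf replicate 2. Not past the threshold were buc (804 CPM at 3 dpf against 770 at 1 dpf), ddx4 (251 against 235), hwa (72.6 against 58.7) and btg4 (-0.49, adjusted p = 0.174), of which btg4 passed with the replicate block (-0.5). The nanos3 copy LOC110495041 (2.97, adjusted p = 0.0647) also passed with that block (3.22).

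The edgeR test called 1892 genes higher and 738 lower at 3 dpf than at 1 dpf among 23460, and of these 1431 and 119 differed at least 2-fold. With the replicate number as a block, which took these replicates as paired, the counts were 2086 and 984, and with that block and the 0 hpf libraries left out 2963 and 1419. Without the libraries numbered 3 of the later stages they were 1076 and 169, and without 1 dpf replicate 1, 1 dpf replicate 2 and 3 dpf replicate 1 in turn 1230, 1042 and 970 genes were higher. Fewer genes were lower without 1 dpf replicates 1, 2 and 3 (291, 390 and 344) and without 3 dpf replicates 1 and 3 (256 and 302), and DESeq2 called 1240 lower.

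**Figure D3:**
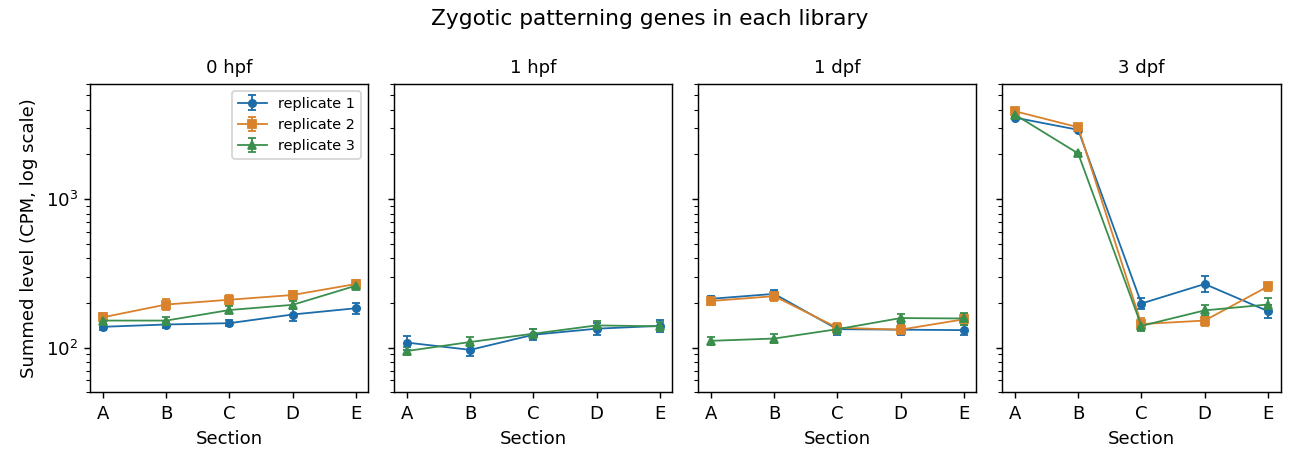
Summed level of the zygotic patterning list (CPM, log scale, y axis) in sections A to E (x axis) of each library at the 4 stages, with 95% Poisson intervals that cover counting error only. At 1 dpf replicates 1 and 2 stood at 213 and 206 CPM in section A and replicate 3 at 111, and at 3 dpf all 3 replicates stood between 3540 and 3910.

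From 0 to 1 hpf 45 genes changed in A minus E, measured as the difference between stages, and 845 (3.6% of 23458) when all 4 section terms were tested together, a test chosen after the data had been seen. The LIM-domain gene limd2 moved toward A by 2.93 (SE 0.34, A minus E from -4.15 to -1.24, adjusted p = 2.98e-06). The elongation complex gene ice2 moved by 2.35 (SE 0.34, from -1.94 to 0.3, 0.000225) and hapstr1a by 1.97, both lost without 1 hpf replicate 3. Toward E moved the homeobox gene mkxa (adjusted p = 0.0195, without a count in E at 0 hpf and so given without a size), lost without either 1 hpf replicate or 0 hpf replicate 1 or 3. The transcription factor bach1b (-3.8, SE 0.74) was lost without 1 hpf replicate 3 (-2.07) or 0 hpf replicate 2 or 3, and was at -5.33 without 1 hpf replicate 1. The gene ralgapa1, which encodes a subunit of the Ral GTPase-activating complex, moved by -3.5 (SE 0.34, from 1.39 to -2, adjusted p = 2.91e-08). Not past the threshold were dazl (-0.99, adjusted p = 0.688) and ddx4 (-0.51, 0.578). As a group the ribosomal proteins leaned toward A without a called member (median 0.72, camera adjusted p = 1.39e-18, adjusted p = 0.25 with an estimated correlation). The germ plasm list leaned toward E (median -0.18, camera adjusted p = 0.0295, adjusted p = 0.453 with an estimated correlation). Of the 45 genes 18 moved toward A and 27 toward E, with 1668 at an unadjusted p under 0.05. DESeq2 called 79, the fit without the replicate term 5, and leaving out 0 hpf replicates 1, 2 and 3 in turn 31, 71 and 14. Without 1 hpf replicate 1 there were 20 and without 1 hpf replicate 3 there were 3.

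From 1 hpf to 1 dpf the test called 1 gene, the unnamed LOC110504686, which moved toward A (adjusted p = 0.0296, with 3 counts or fewer in A at 1 hpf) and is named here after its value was seen. At an unadjusted p under 0.05 there were 1050 genes, DESeq2 called 2, and without 1 dpf replicate 3 there were 43. The fits without any other single replicate of these stages called 0, as did the fit without the replicate term.

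From 1 to 3 dpf a large part of the transcriptome changed in A minus E. Toward E moved boka, a pro-apoptotic member of the BCL2 family, by -3.62 (SE 0.34, A minus E from 1.02 to -2.57, adjusted p = 9.31e-11). It was followed by the zinc-finger gene ZNF22 (LOC118938416, -3.6, SE 0.56) and the dynein adaptor hook1 (-3.42, SE 0.41), which were at -4.24 and -4.12 without 3 dpf replicate 1. The zinc-finger factor klf6a moved by -3.28 (SE 0.28, from 1.34 to -1.9), the choline transporter gene slc44a4 by -3.22 (SE 0.3, from 0.53 to -2.64) and tshz2 by -3.17 (from 1.18 to -2.01). Ranked first toward A by the fitted value were cspg4b (adjusted p = 0.00012), the matricellular gene ccn1l2 (0.0366), flrt3 (0.0433), the caveolin gene cav1 (0.00203) and btg1 (0.00188). Each had 3 counts or fewer in section A or E of at least 1 of the stages, so no size is given. Of these, ccn1l2 was lost without 1 dpf replicate 3 or 3 dpf replicate 2, flrt3 without any 1 dpf replicate or 3 dpf replicate 2, and cav1 without 1 dpf replicate 1.

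Oocyte genes moved toward E from 1 to 3 dpf in 18 of 26 cases and toward A in 0 (18 and 0 adjusted over the list alone), with a median of -1.18. Against all other genes camera gave an adjusted p of 1.32e-07, and adjusted p = 0.098 with an estimated correlation. Among them were btg4 (-2.46, from -1.09 to -3.54), figla (-1.94), zar1 (-2.14, or -2.77 without 3 dpf replicate 1) and zar1l (-1.77, from 1.98 to 0.2). Ribosomal protein genes moved toward A in 130 of 145 cases (134 adjusted over the list alone), for instance rl7 (3.13, from 1.24 to 4.52). The camera test returned an adjusted p of 2.73e-28, and adjusted p = 0.138 with an estimated correlation. The endoplasmic reticulum chaperone grp94 (2.16, from -1.42 to 0.73) and the variant histone h2ax (2.78, from -1.18 to 1.49) crossed from a vegetal to an animal excess. The chaperone hspa5 moved by 2.17 (from -1.72 to 0.45) and lost its vegetal excess, but did not differ past the threshold between A and E at 3 dpf. The cyclin ccna1 (-2.35, from -1.13 to -3.55) and sox3 (-1.97) moved toward E.

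Of 44 zygotic patterning genes 12 moved toward A and 2 toward E from 1 to 3 dpf (10 and 2 adjusted over the list alone, camera adjusted p = 1.2e-08, adjusted p = 0.171 with an estimated correlation). Of 70 genome activation regulators 34 moved toward A and 8 toward E (39 and 8 adjusted over the list alone, camera adjusted p = 0.000956, adjusted p = 0.438 with an estimated correlation). Here nanog LOC110535236 moved by 2.73 (from 1.78 to 5.29), with 3.56 without 1 dpf replicate 1, 3.44 without 3 dpf replicate 2 and 1.84 without 1 dpf replicate 3. The factor pou5f3 moved by 1.69 and the insulator gene ctcf by 1.72 (from -0.08 to 1.63). Of 65 clearance genes 35 moved toward A and 10 toward E (37 and 10 adjusted over the list alone, camera adjusted p = 0.00207, adjusted p = 0.51 with an estimated correlation), with ago2 (the gene other than LOC110488009) at 3.67. Of 24 envelope genes 12 moved toward A and 3 toward E (12 and 3 adjusted over the list alone, camera adjusted p = 0.00491, adjusted p = 0.098 with an estimated correlation), with the grhl3 copy LOC110498393 at 2.89.

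Of 29 germ plasm genes 3 moved toward A and 7 toward E from 1 to 3 dpf (3 and 7 adjusted over the list alone, camera adjusted p = 0.567). The gene buc moved toward E (-1, and -1.25 for the copy LOC110535186), while its copy LOC110489830 (-0.8, adjusted p = 0.0804) passed only with library-size scaling (-1.2), without 1 dpf replicate 3 (-1.12) or without 3 dpf replicate 1 (-1.19). Toward A moved dazap2 LOC110532562 (1.48, adjusted p = 2.36e-06) and dnd1 (0.77, 0.00427), and dnd1 was lost with library-size scaling (0.37) or without 3 dpf replicate 3 (0.44). Not past the threshold were dazl (-0.55, adjusted p = 0.327, or -1.45 and past it without 3 dpf replicate 1), the grip2a/grip2b gene LOC110492486 (-0.65, 0.501), hwa (-1.08, 0.419) and ddx4 (0.41, 0.085, or 0.53 and past it without 3 dpf replicate 2). The edgeR test called 10309 of 23458 genes (43.9%), 5343 toward A and 4966 toward E. With library sizes in place of TMM factors the split was 3406 toward A and 7617 toward E, so the balance of the directions depends on the scaling.

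Over the whole series, from 0 hpf to 3 dpf, bach1b moved toward E by -4.91 (SE 0.72, with -5.82 without 3 dpf replicate 1 and -4.23 without 3 dpf replicate 3) and boka by -4.11 (SE 0.35, from 1.52 to -2.57, adjusted p = 3.76e-12). The zinc-finger gene ZNF22 LOC118938416 moved by -3.93, or -4.54 without 3 dpf replicate 1. Also called toward E were mkxa (adjusted p = 8.26e-06), sntg1 (0.000175) and rgma LOC110495562 (0.000645), which had 3 counts or fewer in a pole of 1 of the stages and are given without a size, and mkxa and sntg1 were lost without the replicate term. Ranked first toward A by the fitted value were hnf4a (adjusted p = 0.0231, lost without 0 hpf replicate 1 or 3), btg1 (0.000273, lost without 0 hpf replicate 3) and the amino acid transporter slc7a7 LOC110531642 (8.4e-05), again without a size for the same reason. Ribosomal protein genes moved toward A in 144 of 145 cases (median 3.77, camera adjusted p = 6.16e-36, adjusted p = 0.098 with an estimated correlation). Oocyte genes moved toward E in 17 of 26 cases and toward A in 1 (20 and 1 adjusted over the list alone, camera adjusted p = 1.76e-06, adjusted p = 0.098 with an estimated correlation), with btg4 at -2.88. The cyclins ccna1 and ccnd2b moved toward E (-2.75 and -2.72), while the signal bmp4 (2.02), grhl3 (5.56) and its copy LOC110498393 (3.81), h2ax (3.08) and grp94 (2.8) moved toward A. The edgeR test called 11521 of 23458 genes (49.1%), 5928 toward A and 5593 toward E, or 4612 and 7331 with library-size scaling.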

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

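The tests of depth and of swapped labels for 1 dpf replicate 3, the benchmark of the parents test, the test of all 4 section terms for change of position and the counts over other splits of the libraries were chosen only after the results they test had been seen.

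The difference between section A and section E was not the same at all stages, by a test of the change itself. It changed for 45 genes from 0 to 1 hpf, for 1 gene from 1 hpf to 1 dpf, for 10309 from 1 to 3 dpf and for 11521 from 0 hpf to 3 dpf. With all 4 section terms tested together, beyond A and E, it was 845, 6, 12110 and 14527 genes. From 0 to 1 hpf limd2 (2.93), ice2 (2.35) and hapstr1a (1.97) moved toward A, and bach1b (-3.8), ralgapa1 (-3.5) and crebl2 (-2.29) toward E. Of these, limd2 and ralgapa1 kept their calls without any single replicate, and crebl2 was lost without any of the 0 hpf replicates or without 1 hpf replicate 3 (-1.41). From 1 to 3 dpf boka (-3.62), ZNF22 LOC118938416 (-3.6) and hook1 (-3.42) moved toward E. From 0 hpf to 3 dpf bach1b (-4.91), boka (-4.11) and ZNF22 LOC118938416 (-3.93) did so.

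Other splits of the same libraries were counted for the larger results. For genes localized over the sections, the real assignment was the only 1 of 40 drawn to give as many genes at 0 hpf (12226, highest other 3495), at 1 dpf (13810, highest other 38) and at 3 dpf (15622, highest other 12442). A share of 1 in 40 is under 0.05 and is the smallest that 40 draws can give. The draws shuffled sections within replicates and can keep part of the real order, so a high count in a draw is not free of real differences. Section A against E gave 13946, 14036 and 16211 genes at 0 hpf, 1 dpf and 3 dpf, against 0, 4 and 0 in the highest other of the 10 splits. Genes changed in total from 1 to 3 dpf numbered 2630, with 0 in the highest other split, and of the 4 splits that part all 3 pairs of replicates the other 3 gave 0. Genes redistributed from 1 to 3 dpf numbered 10309 (highest other 5) and from 0 hpf to 3 dpf 11521 (highest other 265). With 10 splits a share under 0.1 cannot be reached in these tests.

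The 1 dpf replicate numbered 3 stood at 111 CPM for the zygotic patterning list in section A, and replicates 1 and 2 at 213 and 206. Lower depth is argued against, since section A of replicate 3 had 8.0 M counts, against 6.06 and 5.09 M in replicates 1 and 2. The upper 95% Poisson bound of replicate 3 was 118 CPM, below 206. A swap with a 1 hpf replicate of the count table is argued against as well, since the highest of these stood at 108 CPM (upper bound 119), below both other 1 dpf replicates. Across genes its deviations followed those of the later samples numbered 3 (r = 0.66 with 1 hpf replicate 3, 0.72 with 3 dpf replicate 3 and -0.47 with 3 dpf replicate 2), which speaks against a swap with 1 hpf replicate 2 if that sample resembled the later ones of its number. As 1 hpf replicate 2 was not analysed here, that swap stays open, and so does slower development of the sample.

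Of the 816 genes that differed in total between 0 and 1 hpf, 516 higher and 241 lower ones were tested along the axis at 1 hpf. Transcription in the animal pole was set beforehand to need most of the higher genes above E in section A. The share was 24.6% of the higher genes (68.9% of the lower and 51.4% of all genes). The sums weight sections by depth, and D and E were the shallowest sections of 0 hpf replicates 1 and 3. That weighting could also give such shares and was not tested. The shares therefore do not decide on this cause and do not show where transcription took place. Of 167 copies 0% changed past the threshold in the opposite direction. Reads moving between copies stay open all the same. The stage test recovered 1% of simulated 2-fold changes and called 816 of 23460 genes, so a low share was likely either way. Different positions of the sections along the axis are argued against as the whole cause, since 27.5% of the called genes (180 of 655, against 29% of all genes) differed by less than 0.5 log2 between A and E at both stages. Different parents of the 0 hpf and later samples cannot be told from stage. Of the called genes 100% kept the sign of their difference from 0 hpf at 1 dpf and 98.4% at 3 dpf, which either could give. The median SD of the called genes between later replicates was 0.169, at percentile 0 of 10000 matched random sets (median 0.233, maximum 0.26). This result had been set beforehand to count against different parents. That criterion was set aside afterwards, because the labels do not say that the later replicates had different parents from each other. A low spread between them therefore excludes nothing. The genes were also called in 1 fit of all 11 sums, where a low spread between later replicates favours a call. The low percentile may thus come from the selection. The benchmark added afterwards, the genes called between 3 dpf and 1 dpf, stood at percentile 100 (0.253 against 0.232).

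The 4966 genes that moved toward E from 1 to 3 dpf had a median shift of -1.28 in A minus E (interquartile range -1.7 to -0.93). Loss from section A with retention in section E had the values it needs, with a median change in relative level of -1.24 in A and 0.03 in E. These genes were selected for a fall in A minus E, which fixes the difference but not its division between A and E. The genes that moved toward A changed by 1.38 in A and -0.07 in E, so a flat level in E was not particular to the genes that moved toward E. Dilution of maternal transcripts in section A by 1 common factor cannot be told apart from it, since the spread of the shifts was 2.96 times the median standard error of 0.26, between the limits set beforehand. Each library came from the same mass of RNA, so these are relative levels, and with library-size scaling 7617 genes moved toward E and 3406 toward A.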

How the results depend on the processing

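Alternatives chosen after the data had been seen were the replicate block with the 0 hpf sums left out, the libraries numbered 3 of the later stages left out together, the test of all 4 section terms for redistribution, and the step shares at 50 CPM or with a prior count of 5. The cause of the differences below was not tested except where fewer samples or a stricter threshold enter by construction. Over all alternatives 181 counts stayed within 1.5 times, 61 moved further, 4 rose from 0 and 5 fell to 0. Of the results of single genes (1084 gene and comparison pairs), 10792 kept their side of the threshold, 387 lost and 175 gained a call, and 0 called genes reversed. Of the 10792, 218 changed sign while past the threshold in neither fit, and the others kept their direction. Of the list results, 458 stayed, 61 lost a call, 58 of them with an estimated correlation, and 6 gained one. The other losses were clearance genes from 0 hpf to 3 dpf (0.0622) and ribosomal proteins from 1 hpf to 1 dpf (0.117) in redistribution with library-size scaling, and follicle markers from 0 to 1 hpf with the replicate block (0.0993). Library-size scaling gave a call to the clearance list at 0 hpf (0.0429, and 0.0293 without the replicate term), to genome activation regulators from 0 to 1 hpf (0.0429) and to vegetal determinants (0.0389, 0 to 1 hpf), liver and yolk precursors (0.0429, 1 to 3 dpf) and stress genes (0.0425, 0 hpf to 3 dpf) in redistribution. The share of the step from B to C was 31.6, 66.5, 87 and 30.5% at 50 CPM and 30, 67.8, 87.6 and 35.4% with a prior count of 5, at 0 hpf, 1 hpf, 1 dpf and 3 dpf. Without the replicate block within a stage, localized genes numbered 7743 at 0 hpf and 4227 at 1 hpf, and at 1 hpf 3191 were higher in A and 2974 in E. A minimum change of 2-fold gave 7068 and 8375 localized genes at 0 hpf and 1 dpf. It gave 3806, 3790 and 4403 higher in A and 3177, 2890 and 3177 higher in E at 0 hpf, 1 hpf and 1 dpf. Leaving out a replicate gave 7490 (number 3) to 10763 localized genes at 0 hpf, and at 1 hpf 3136 (without replicate 3) to 4144 higher in A and 3536 (without replicate 3) to 4392 higher in E. For 1 hpf against 0 hpf the higher and lower genes were 1053 and 769 with the replicate block across stages, 21 and 13 with only these stages, 833 and 1235 without the later libraries numbered 3, 786 and 587 with each section weighted alike, and 1464 and 1468 with DESeq2. At least 2-fold higher were 315, and leaving out a replicate gave 117 (without 0 hpf replicate 3) to 1887 (without 0 hpf replicate 2) higher and 32 (without 1 hpf replicate 1) to 1220 (without 0 hpf replicate 2) lower. For 1 dpf against 1 hpf DESeq2 gave 10 and 1 where edgeR gave 0 and 0 (679 genes at an unadjusted p under 0.05), and leaving out a replicate gave 0 to 97 and 0 to 5, the upper values without 1 dpf replicate 3. For 3 dpf against 1 dpf, whose numbers were taken to pair the samples, the replicate block gave 2086 higher and 984 lower and changed the calls of btg4 and 1 nanos3 copy but of no list or other named gene. With that block and 0 hpf left out there were 2963 and 1419, without the libraries numbered 3 1076 and 169, and DESeq2 gave 1240 lower and a minimum of 2-fold 119 lower. Leaving out a replicate gave 970 (without 3 dpf replicate 1) to 1827 higher and 256 (without 3 dpf replicate 1) to 546 lower. Redistribution from 0 to 1 hpf was called for 5 genes without the replicate block, 79 with DESeq2, 845 with the test of all 4 section terms and 3 (without 1 hpf replicate 3) to 71 (without 0 hpf replicate 2) with a replicate left out. From 1 hpf to 1 dpf it was called for 0 genes without the replicate block, 8 without the libraries numbered 3, 2 with DESeq2, 6 with all 4 section terms, and 0 to 43 (without 1 dpf replicate 3) with a replicate left out. With all 4 terms 12110 and 14527 genes changed from 1 to 3 dpf and from 0 hpf to 3 dpf. Numbers did not pair the samples of 0 hpf by the rule, and for 1 hpf only 2 pairs exist. The samples numbered 3 stood apart in all later stages, whereas numbers 1 and 2 were not cleanly told apart (1 hpf replicate 1 correlated with 1 dpf replicate 2 at 0.62 and with 1 dpf replicate 1 at 0.58). On simulated counts the stage tests recovered 1 to 8% of 2-fold changes, and depth, replicate spread and replicate number were not separated as limits of that share. Depth by itself sets the level below which a gene at 0 counts in a library lies, 0.207 to 2.752 CPM.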

Other observations

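The test of gene copies at 0 hpf was set before its result was seen, and no test in this part was chosen afterwards.

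From 1 to 3 dpf 10 of 32 genes of the vegetal and dorsal determinant list rose and 2 fell (13 and 3 adjusted over the list alone). The list's camera adjusted p was 0.000272, and adjusted p = 0.172 with an estimated correlation. The Nodal ligand ndr2 was at 6.16 (SE 0.81, 14.8 against 0.204 CPM, adjusted p = 0.00146, n = 3) and the mesendoderm factor eomesb at 2.6 (119 against 19.5 CPM), whereas the kinesin kif5ba/kif5bb fell by 1.04 (62.8 against 128 CPM). The maternal hwa (0.3, adjusted p = 0.357) and grip2a/grip2b LOC110492486 (0.03, 0.977) did not pass. In the stress and immediate-early list 7 of 25 genes rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.141), with the chaperones hspa8 at 2.38 (798 against 152 CPM) and hsp90ab1 at 2.24 (841 against 176 CPM). Histone genes rose in 4 of 5 cases (4 adjusted over the list alone, camera adjusted p = 0.00671, adjusted p = 0.289 with an estimated correlation), among them h2ax (0.89) and h2ax1 (1.63).

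Clearance genes rose in 7 of 65 cases and fell in 1 from 1 to 3 dpf (9 and 1 adjusted over the list alone, camera adjusted p = 0.108). The Argonaute copy ago2 LOC110488009 was at 4.15 (149 against 8.35 CPM). Envelope and periderm genes rose in 4 of 24 cases and fell in 1 (7 and 3 adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.289 with an estimated correlation). The keratin krt5 was at least 120-fold higher (4.66 CPM), and klf6a fell by 0.97, a call lost without 3 dpf replicate 1 or 2. In the cell cycle list 9 of 68 genes rose and 8 fell (12 and 8 adjusted over the list alone, camera adjusted p = 0.745). There the cell cycle inhibitor cdkn1a was at 5.68 (8.2 against 0.154 CPM), the replication inhibitor gmnn at 1.47 (374 against 134 CPM) and the mitotic ubiquitin-conjugating gene ube2c at -0.93 (43.3 against 81.8 CPM). Of 55 localization and motor genes 7 rose and 4 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.526), with the RNA-binding gene ptbp1a at 0.98 and 1.11 for its copies. Among markers of other cells 1 of 4 liver and yolk precursor genes rose (2 adjusted over the list alone, camera adjusted p = 0.0351, adjusted p = 0.248 with an estimated correlation), namely apoa-i-1. Of 7 sperm and testis genes odf2a rose (2.73) and odf2b fell (-0.67).

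Trout carry many gene copies that share a zebrafish ortholog, and a hypothesis is that such copies keep the localization of their common ancestor. Across 2136 pairs of copies at 0 hpf, A minus E correlated with Pearson r = 0.67 and Spearman rho = 0.67. A permutation test of random pairings gave p = 1e-05, the smallest that 100000 permutations can give, and the largest permuted value was 0.1. This correlation is across genes, which are not independent replicates, and reads shared between similar copies could also raise it. Of 1391 pairs with both copies called, 1189 lay at the same pole and 202 at opposite poles. Examples chosen after their values were seen were klhl8 (-5.78 and 0.62), larp4b (-2.68 and 2.97), myo18ab (1.48 and -4.32) and usp24 (2.04 and -2.9), which reads shared between copies would draw together rather than apart.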
